A study of Arabidopsis thaliana with 18 samples.

How the data were processed

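Rosettes of wild type (WT) and era1 Arabidopsis thaliana were harvested at Boyes stage 5.10 from plants grown on potting soil with nitrate at 0, 2 or 10 mM, per the labels' protocols. The titles gave genotype, dose and replicate number, which set 6 groups of 3 libraries. The series text calls them biological replicates. It also mentions an ecotype comparison, but the labels used here name no ecotype, so none was analysed here.

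Libraries were made from polyA-selected RNA with a QuantSeq 3' kit, single-end and stranded, per the labels' protocols. TopHat2 and the TAIR10 assembly are named per the submitters' processing notes. Their versions, the annotation, the trimming and the mapping settings are not given in the sources used here, nor is the strand setting of the counting. Genes that overlap or lie antisense to another gene are therefore uncertain. The authors deposited raw read counts per gene for each library, with no normalization, in the layout that HTSeq writes. Each library held 32744 genes and 5 summary counters. These counters name no gene and were left out of library sizes and tests. By group they took 3.95% to 5.43% of read records for reads outside genes and 2.15% to 4.97% for reads without a unique alignment, and in single libraries 0.116% to 0.141% for ambiguous reads. Reads shared by near-identical gene copies were thus set aside before counting, and members of such families (RBCS, LHCB1, PDF1.2) are uncertain. A 3' kit counts tags near the transcript end, so counts were not scaled by gene length.

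Gene totals ran from 4748044 to 6306900 per library. Counts within a group were compared pair by pair, over genes with at least 20 counts in the pair. Chi-square per degree of freedom ran from 1.50 to 4.44, so each pair differed by more than sampling noise. Gene names came from a RefSeq table of the assembly TAIR10.1. It differs from the build of the files and was used for names only, with no coordinates. Of 32744 gene IDs 32548 matched it and 10804 had a symbol.

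Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest with defaults). Libraries were scaled by trimmed mean of M values (TMM). Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 18358 genes, 8123 of them with a symbol. A single model of the 6 groups over 18 libraries gave 12 contrasts. These were each pair of doses within a genotype, era1 against WT at each dose and averaged over doses, and the interactions of genotype with 0 and with 2 against 10 mM. P-values were adjusted by Benjamini-Hochberg within each contrast, at a threshold of 0.05 for the FDR. Exact permutation tests of single values were two-sided.

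The named genes followed a fixed rule. In the main contrasts they were up to 10 with the highest and 10 with the lowest log2 fold change. Those had to pass the FDR threshold, have a mean of at least 5 CPM and a symbol, and, except in the average and the interaction, show no overlap between the groups compared. From each list up to 4 members with the largest change past the threshold were taken, and members with the opposite direction. ERA1, the other farnesyltransferase and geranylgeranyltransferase subunits and the locus printed in the genotype label were always included. The clock outputs and metal genes lie outside that rule. The clock outputs were chosen after the core clock genes, and the metal genes after bHLH38, bHLH39, BHLH100 and FSD1, had been seen, but before their own tests were run.

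The 20 gene lists were nitrate transport, nitrate-induced response and assimilation, nitrogen remobilisation with ammonium, urea and amino acid uptake, autophagy, leaf senescence, anthocyanin and flavonoid synthesis, nuclear photosynthesis genes, abscisic acid response, salicylic acid response and pathogen defence, jasmonic acid response, protein prenylation and isoprenoid supply, farnesylated proteins, flowering time and floral organs, root markers, phosphate starvation response, ribosome and ribosome biogenesis, glucosinolate synthesis, heat shock response, circadian clock and starch and sugar metabolism. Of 396 members written, 382 matched the reference table by ID and name, and 14 were dropped. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with adjustment over the 19 tested lists per contrast. Of 104 calls over the 12 contrasts, 0 held in camera with an estimated correlation. That setting had 0 to 5 lists per contrast at an unadjusted p under 0.05, and the self-contained test fry called 6 to 18. Median, mean and camera direction differed in sign for 28 of 228 combinations of list and contrast, 0 of them called.

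The scripts were tested on simulated counts over 18053 genes. For WT at 0 against 10 mM, 58.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 10 of 17822 unchanged genes were called. For the interaction at 0 mM the shares were 25.4%, 67.2% and 93.9%, with 12 unchanged genes called. With no simulated change between genotypes at 10 mM, 1 unchanged gene was called.

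Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, the DESeq2 test, limma-voom, no expression filter, a mean of at least 5 CPM, only the groups compared, a replicate block, leaving out each library, nuclear genes only, an estimated inter-gene correlation, fry, and, chosen after the clock genes were seen, leaving out the libraries grown at 2 mM. Figures were drawn with matplotlib 3.10.9.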

Results

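Rosettes of Arabidopsis thaliana were profiled by 3' messenger RNA tag sequencing in wild type (WT) plants and in the era1 mutant, each grown on potting soil with nitrate at 0, 2 or 10 mM. ERA1 encodes the beta subunit of protein farnesyltransferase, which attaches a farnesyl lipid to proteins with a C-terminal CaaX motif, and the series title places the study in adaptation to nitrogen starvation. The design held 6 groups of 3 libraries, 18 in all, harvested at the stage of the first visible flower buds. The libraries held 4748044 to 6306900 gene counts each, with 20738 to 21486 genes detected per library. The 10 most abundant genes took 2.53% to 3.96% of the counts of a library. Levels are given as CPM, the counts of a gene scaled to a common library size, mean ± SD with n = 3 libraries per group. Log2 fold changes are given ± SE with the false discovery rate (FDR) of edgeR, and list medians are medians of log2 fold changes. The series text calls the libraries of a group biological replicates without saying whether they came from separate plants or pools, so the p-values measure only the spread between these samples.

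The mutated gene was examined first. ERA1 (AT5G40280) had 42 to 54 counts in each WT library and 6 to 17 in each era1 library. In WT its level was 9.26 ± 0.453 CPM at 10 mM, 11.1 ± 0.590 at 2 mM and 9.50 ± 0.758 at 0 mM, and in era1 it was 1.39 ± 0.295, 2.21 ± 0.545 and 2.29 ± 0.407 CPM. The log2 fold change of era1 against WT was -2.71 ± 0.23 at 10 mM (FDR = 3.5e-09), -2.33 ± 0.21 at 2 mM (FDR = 1.1e-08) and -2.04 ± 0.20 at 0 mM (FDR = 9.4e-09). Each era1 library lay below each WT library. A 3' tag can persist beside an insertion, so the remaining counts do not measure functional transcript. The genotype label prints another locus, AT5G66470, which was measured in parallel. Its level in WT and era1 was 44.5 ± 2.2 and 40.9 ± 2.95 CPM at 10 mM, 35.0 ± 6.64 and 28.9 ± 0.791 at 2 mM, and 27.4 ± 5.41 and 17.0 ± 3.22 at 0 mM. The genotypes differed at this locus at 0 mM (-0.69 ± 0.15, FDR = 4.6e-04), while the test was not passed at 10 mM (-0.12, FDR = 0.514) or 2 mM (-0.28, FDR = 0.164). The shared alpha subunit FTA (AT3G59380) did not pass the test at 10 mM (-0.29, FDR = 0.0675), 2 mM (0.08) or 0 mM (0.08), though without the era1 library 2 at 10 mM the value there was -0.37 and passed. The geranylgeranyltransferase beta subunit PGGT-I (AT2G39550) was at 0.18, 0.06 and -0.04, with no test passed.

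**Figure D1:**
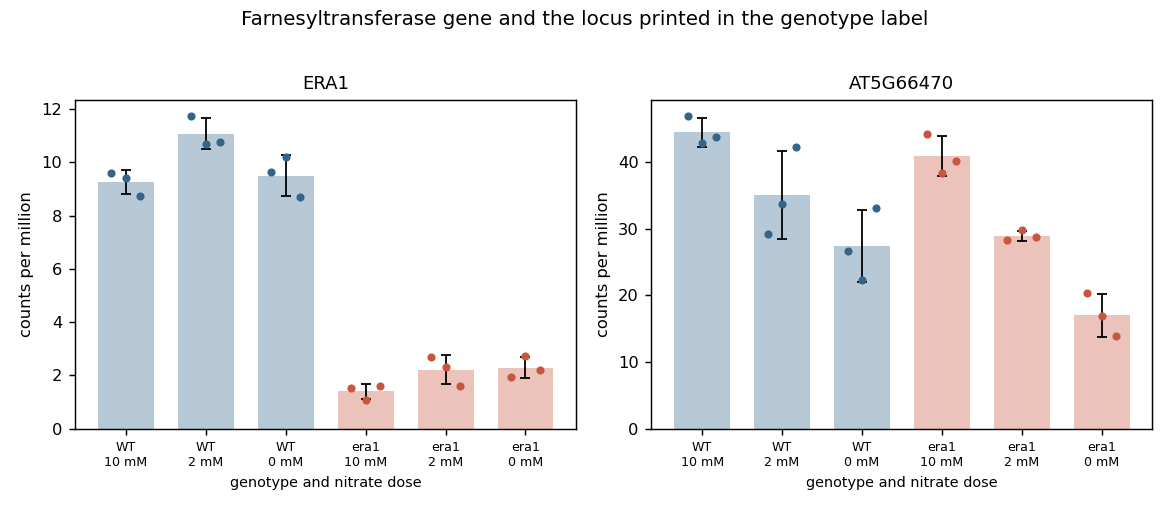
CPM (vertical axis) of ERA1 and of the locus printed in the genotype label, by genotype and nitrate dose; points are single libraries, bars the mean of 3 and error bars the SD. ERA1 lay between 1.39 and 2.29 CPM on average in era1 and between 9.26 and 11.1 CPM in WT.

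The first principal component of the log2 CPM held 35.5% of the variance and set the 6 libraries grown at 2 mM apart, in both genotypes, from all others, while the second held 29.7%. Core clock genes moved with that separation. The morning-expressed LHY (AT1G01060) was at 477 ± 15.5 CPM at 10 mM, 29.4 ± 4.48 at 2 mM and 740.0 at 0 mM in WT, and at 432, 35.9 and 723 CPM in era1. CCA1 (AT2G46830) was likewise at 15.4 CPM at 2 mM in WT, against 102 at 10 mM and 245 at 0 mM. Over the WT libraries at 10 mM the evening genes FKF1 (AT1G68050) and PRR5 (AT5G24470) had 0 and 1 counts. At 2 mM FKF1 was at least 70.3-fold higher, and PRR5 had a ratio of 185 (32.9 to 7366) (log2 fold change 7.12, and 9.13 without the WT library 3 at 10 mM). Folds against groups without counts were set against a floor of 3 counts over the group, and such intervals are at 95% and cover counting error only. Over clock outputs outside the core clock list, chosen after the core clock genes were seen, the evening median log2 fold change at 0 against 10 mM minus the morning median was -0.15 in WT (95% bootstrap interval -1.1 to 0.92) and 0.10 in era1 (-0.57 to 0.67). The share of read records without a unique alignment was lower at 10 mM than at 2 and 0 mM, which were alike. In WT it was 2.15 ± 0.222% at 10 mM, 4.88 ± 0.137% at 2 mM and 4.97 ± 0.245% at 0 mM, and in era1 2.52 ± 0.261%, 4.72 ± 0.281% and 4.74 ± 0.519% (exact permutation p = 0.1 for each dose against 10 mM, the smallest that 3 against 3 libraries allow). Organelle genes took 2.09% of gene counts in WT at 10 mM, 3.95% at 2 mM and 4.13% at 0 mM. What set the 10 mM libraries apart in these shares was not tested, so a cause other than dose stays open.

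**Figure D2:**
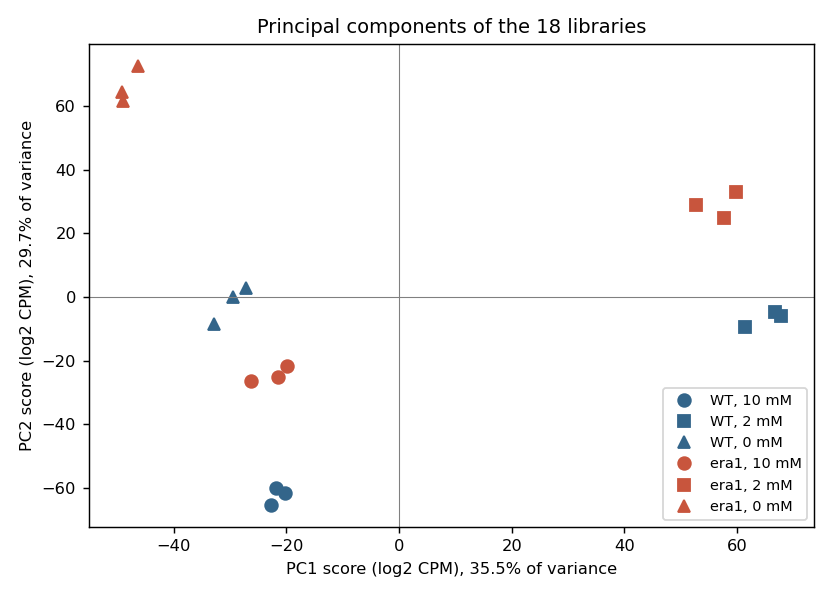
Scores of the 18 libraries on the first and second principal components of log2 CPM (35.5% and 29.7% of the variance); colour gives the genotype and the marker shape the nitrate dose. The libraries grown at 2 mM stand at scores of 52.7 to 67.9 on the first component and all others below 0.

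**Figure D3:**
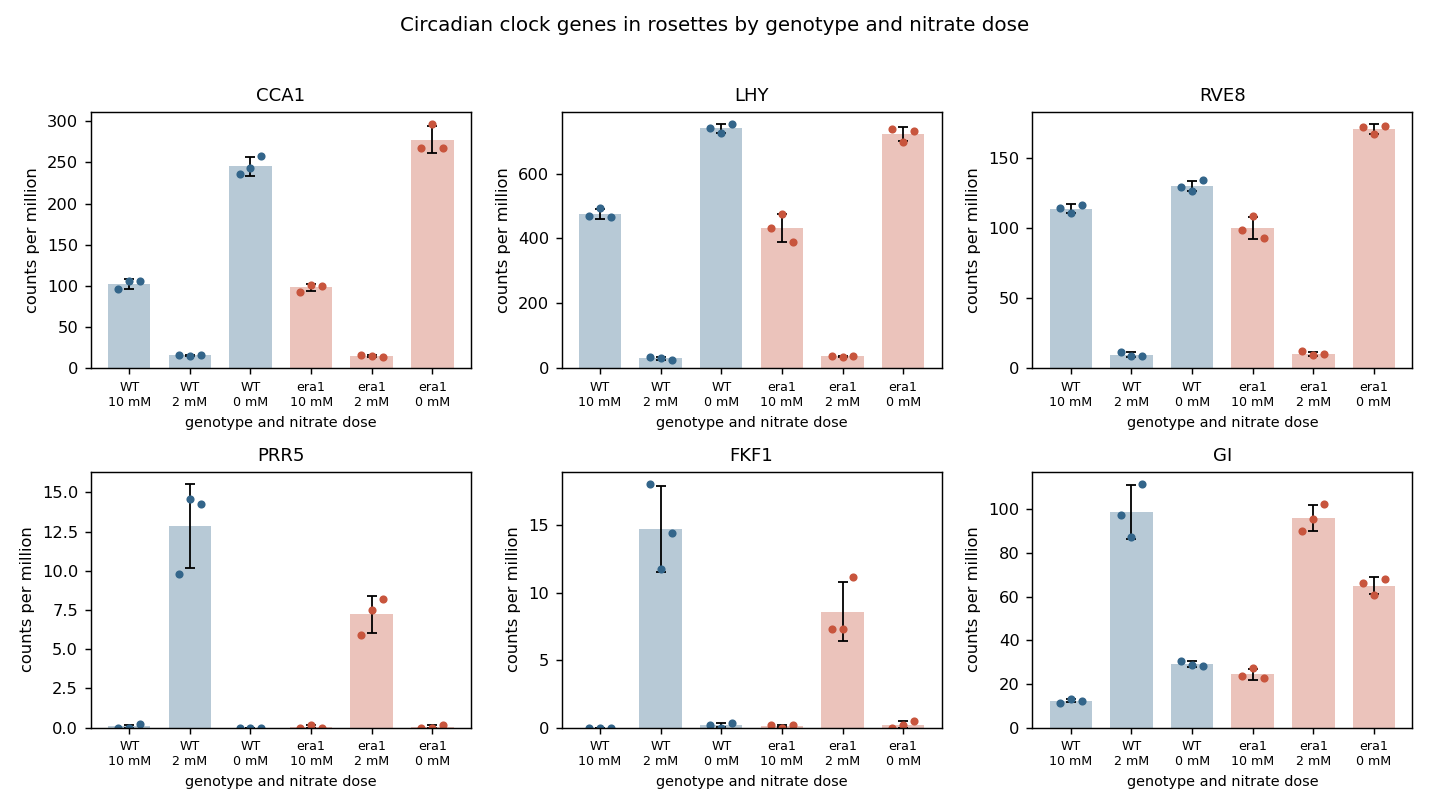
CPM (vertical axis) of 6 clock genes by genotype and nitrate dose; points are single libraries, bars the mean of 3 and error bars the SD. In WT, LHY was at 29.4 CPM at 2 mM and at 477 CPM at 10 mM.

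The response of WT to nitrate dose was read from 0 against 10 mM. Clock genes also moved between these doses (LHY from 477 ± 15.5 to 740.0 ± 13.1 CPM), so a different time of day at harvest stays open. At 0 mM, the nitrate transceptor NRT1.1 (AT1G12110) rose from 80.9 ± 1.25 to 221 ± 14.7 CPM (log2 fold change 1.45 ± 0.09, FDR = 3.5e-12). The ammonium transporter AMT1;2 (AT1G64780) rose from 72.4 ± 6.16 to 235 ± 14.6 CPM. Nitrate reductase NIA1 (AT1G77760) fell from 444 ± 69.6 to 69.4 ± 23.3 CPM (-2.68 ± 0.18, FDR = 1.3e-11), and the vacuolar nitrate exchanger CLC-A (AT5G40890) fell from 179 ± 11.4 to 78.8 ± 3.08 CPM (-1.18 ± 0.09). Among the genes with the largest changes, the flowering regulator SPL5 (AT3G15270) rose from 2.02 ± 0.202 to 21.2 ± 1.36 CPM, the kinase of phosphoenolpyruvate carboxylase PPCK1 (AT1G08650) from 2.57 ± 0.190 to 22.0 ± 2.12 and the sugar transporter SWEET13 (AT5G50800) from 2.66 ± 0.886 to 22.1 ± 6.47. The nudix hydrolase NUDT24 (AT5G19470) had no counts at 10 mM and was at least 18.2-fold higher at 0 mM. Among genes with a symbol, decreases included UMAMIT33 (AT4G28040) (from 18.2 ± 3.96 to 0.438 ± 0.277 CPM), NAC004 (AT1G02230) (-4.43 ± 0.24), the nitrate-responsive regulator BT2 (AT3G48360) (from 30.3 ± 10.8 to 1.69 ± 0.935 CPM) and the dark-inducible SEN1 (AT4G35770) (from 60.9 ± 16.0 to 4.15 ± 1.69 CPM). The iron-deficiency regulator bHLH39 (AT3G56980) fell from 83.0 ± 4.0 to 9.76 ± 2.71 CPM and the phosphodiesterase SRG3 (AT3G02040) from 56.0 ± 9.44 to 7.40 ± 1.12. In the edgeR test 9843 of 18358 genes passed, 4945 higher and 4898 lower, and 1444 were higher and 1039 lower by at least 2-fold.

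Gene lists fixed before the data were examined were then followed in WT. Nitrate transport genes rose: 8 of 12 tested members were higher and 1 lower (the same counts adjusted over the list alone), with a median of 1.22. The nitrate transport list had camera adjusted p = 0.0214, and adjusted p = 0.234 with an estimated correlation. With a member lacking counts at 10 mM set at its bound, the median was 1.11. The anion channel SLAH3 (AT5G24030) rose by 2.22 ± 0.18. Nitrate-induced response and assimilation genes fell: 3 of 23 tested members were higher and 13 lower (4 and 13 adjusted over the list alone), with a median of -0.43. Camera gave the nitrate-induced list adjusted p = 0.0323, and adjusted p = 0.601 with an estimated correlation. Leaving out the WT library 2 at 0 mM raised that camera adjusted p to 0.0667. Beside NIA1, the asparagine synthetase ASN2 (AT5G65010) fell from 299 ± 31.4 to 113 ± 10.6 CPM and HRS1 (AT1G13300) was at least 10.3-fold lower, while GLU1 (AT5G04140) rose by 0.30 ± 0.08. Nitrogen remobilisation and uptake genes rose: 9 of 14 tested members were higher and 4 lower (the same counts adjusted over the list alone), with a median of 0.61. The remobilisation and uptake list had camera adjusted p = 0.0498, and adjusted p = 0.426 with an estimated correlation. That call ended without the WT libraries 1 or 3 at 0 mM or 3 at 10 mM (camera adjusted p = 0.0536, 0.0798 and 0.0554), with a replicate block (0.0561) and without the libraries grown at 2 mM (0.0642). The amino acid transporter LHT1 (AT5G40780) rose by 2.29 ± 0.28 and cytosolic glutamine synthetase GSR 1 (AT5G37600) from 8.13 ± 1.28 to 24.6 ± 1.05 CPM, while the asparagine synthetase ASN1 (AT3G47340) (-2.45 ± 0.33) and glutamate dehydrogenase GDH1 (AT5G18170) (-0.55 ± 0.12) fell. Autophagy genes fell: 2 of 21 tested members were higher and 10 lower (the same counts adjusted over the list alone), with a median of -0.20. Camera gave the autophagy list adjusted p = 0.0323, and adjusted p = 0.535 with an estimated correlation. Without the WT library 1 at 0 mM that camera adjusted p was 0.0837. The ubiquitin-like ATG8E (AT2G45170) fell from 66.9 ± 6.12 to 32.7 ± 3.91 CPM.

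Anthocyanin and flavonoid genes rose in WT at 0 mM: 18 of 25 tested members were higher and 2 lower (18 and 3 adjusted over the list alone), with a median of 1.4. The anthocyanin list had camera adjusted p = 2.3e-05, and adjusted p = 0.395 with an estimated correlation. The acyltransferase AT5MAT (AT3G29590) rose by 2.90 ± 0.34, the glycosyltransferase UF3GT (AT5G54060) by 2.64 ± 0.38, and the regulator MYB113 (AT1G66370) was at least 5.76-fold higher (log2 fold change 5.73, and 5.11 without the WT library 1 at 0 mM). C4H (AT2G30490), which acts early in phenylpropanoid synthesis, fell by 0.32 ± 0.08. Starch and sugar genes rose: 10 of 18 tested members were higher and 2 lower (the same counts adjusted over the list alone), with a median of 0.70. Camera gave the starch and sugar list adjusted p = 0.0214, and adjusted p = 0.395 with an estimated correlation. The ADP-glucose pyrophosphorylase subunit APL3 (AT4G39210) rose by 1.95 ± 0.14 and starch synthase GBSS1 (AT1G32900) from 174 ± 6.03 to 530.1 ± 40.0 CPM, while DIN10 (AT5G20250) fell by 1.59 ± 0.25. Salicylic acid and pathogen defence genes fell: 2 of 18 tested members were higher and 11 lower (the same counts adjusted over the list alone), with a median of -0.81. The salicylic acid list had camera adjusted p = 0.0214, and adjusted p = 0.601 with an estimated correlation. In this list NIMIN1 (AT1G02450) fell by 2.23 ± 0.32 and WRKY38 (AT5G22570) by 2.21 ± 0.32. Phosphate starvation genes fell: 1 of 14 tested members were higher and 7 lower (the same counts adjusted over the list alone), with a median of -0.51. Camera gave the phosphate starvation list adjusted p = 0.0214, and adjusted p = 0.395 with an estimated correlation. The noncoding RNA gene AT5G03545 fell from 386 ± 43.3 to 11.2 ± 1.52 CPM and SPX1 (AT5G20150) fell by 1.49 ± 0.13. Ribosome genes fell: 0 of 19 tested members were higher and 12 lower (the same counts adjusted over the list alone), with a median of -0.26. The ribosome list had camera adjusted p = 0.0214, and adjusted p = 0.601 with an estimated correlation. The ribosomal scaffold gene ATARCA (AT1G18080) fell from 611 ± 24.5 to 339 ± 27.1 CPM. Beside these groups stand the organelle share and the share of reads without a unique alignment, which lay higher in each WT library at 0 mM than at 10 mM (exact permutation p = 0.1).

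Other lists moved both ways in WT at 0 mM and were not called. Of the photosynthesis genes, 13 of 32 tested members were higher and 9 lower (the same counts adjusted over the list alone, camera adjusted p = 0.230). Rubisco activase RCA (AT2G39730) rose from 1086 ± 39.0 to 2396 ± 48.5 CPM and the antenna gene LHCA1 (AT3G54890) fell by 0.50 ± 0.07. Of the leaf senescence genes, 7 of 17 tested members were higher and 5 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.627). WRKY53 (AT4G23810) rose by 2.09 ± 0.25 and SAG21 (AT4G02380) fell by 2.05 ± 0.16. Of the abscisic acid genes, 12 of 27 tested members were higher and 6 lower (12 and 7 adjusted over the list alone, camera adjusted p = 0.35). GolS2 (AT1G56600) rose by 1.47 ± 0.12 and COR15A (AT2G42540) fell from 759 ± 25.4 to 203 ± 11.1 CPM. Of the jasmonic acid genes, 8 of 22 tested members were higher and 4 lower (the same counts adjusted over the list alone, camera adjusted p = 0.35), and AOC2 (AT3G25770) fell by 1.54 ± 0.16. PDF1.2 (AT5G44420) rose from 0.626 ± 0.548 to 23.7 ± 25.7 CPM (log2 fold change 5.19, and 3.82 without the WT library 1 at 0 mM). PDF1.2b (AT2G26020) was higher by a ratio of 154 (27.2 to 6102) and PDF1.3 (AT2G26010) by 22.7 (5.97 to 193). Their log2 fold changes were 6.85 and 4.30, and 5.60 and 2.87 without that library. Of the heat shock genes, 6 of 11 tested members were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.621), with a median of 0.31 and a mean of -0.17. Of the glucosinolate genes, 5 of 23 tested members were higher and 7 lower (the same counts adjusted over the list alone, camera adjusted p = 0.982). For prenylation genes, 2 of 14 tested members were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.621). For known farnesylated proteins, 4 of 7 tested members were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.710). For flowering genes, 2 of 10 tested members were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.627), and for clock genes, 5 of 16 tested members were higher and 5 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.997). Camera looks for a common direction and the clock list mixes morning and evening genes, so this p-value cannot decide on a clock shift. In these libraries CCA1 ran from 95.4 to 106 CPM at 10 mM and from 235 to 258 at 0 mM. MYB34 (AT5G60890) rose by 1.44 ± 0.15, the prenylcysteine methyltransferase ATSTE14B (AT5G08335) fell by 0.96 ± 0.17, the co-chaperone J2 (AT5G22060) rose by 0.73 ± 0.11 and the flowering integrator AGL20 (AT2G45660), also known as SOC1, fell from 69.6 ± 8.74 to 22.1 ± 1.18 CPM. Of the root markers, 1 gene, PYK10 (AT3G09260), had enough counts to be tested.

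**Figure D4:**
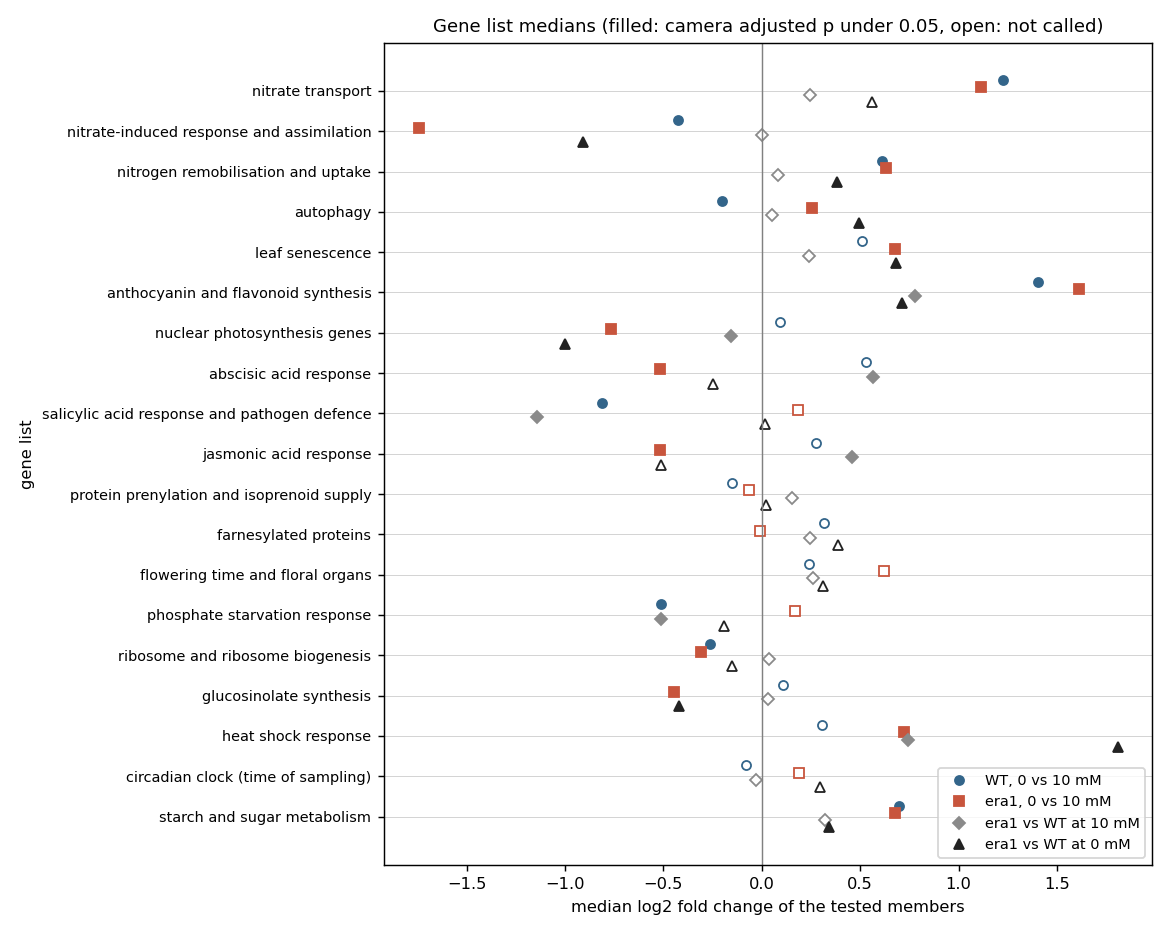
Median log2 fold change (horizontal axis) of the tested members of 19 gene lists in 4 comparisons; filled markers have a camera adjusted p under 0.05 and open markers do not, and 0 of these calls held in camera with an estimated correlation. The photosynthesis list has its median at -1.0 for era1 against WT at 0 mM.

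At 2 mM, WT had less NIA1 than at 10 mM (from 444 ± 69.6 to 61.0 ± 12.4 CPM, FDR = 1.4e-12). LHT1 rose by 3.66 ± 0.24 and GSR 1 from 8.13 ± 1.28 to 65.9 ± 5.95 CPM, AMT1;2 fell from 72.4 ± 6.16 to 8.13 ± 1.33 CPM, and AT5G03545 fell by 3.92 ± 0.18. In the same libraries the clock genes CCA1 fell by 2.73 ± 0.10, LHY by 4.02 ± 0.09 and RVE8 (AT3G09600) by 3.57 ± 0.11. The following lists moved together with them. Photosynthesis genes rose: 27 of 32 tested members were higher and 1 lower (28 and 1 adjusted over the list alone), with a median of 0.50. Camera gave the photosynthesis list adjusted p = 5.6e-07, and adjusted p = 0.465 with an estimated correlation. The antenna gene LHCB5 (AT4G10340) rose from 1255 ± 19.9 to 2875 ± 112 CPM. Anthocyanin and flavonoid genes fell: 1 of 25 tested members were higher and 13 lower (the same counts adjusted over the list alone), with a median of -0.90. The anthocyanin list had camera adjusted p = 0.00200, and adjusted p = 0.465 with an estimated correlation. F3H (AT3G51240) fell from 99.4 ± 1.38 to 11.9 ± 0.980 CPM and TT4 (AT5G13930) by 2.35 ± 0.15. Glucosinolate genes fell: 2 of 23 tested members were higher and 16 lower (3 and 16 adjusted over the list alone), with a median of -0.78. Camera gave the glucosinolate list adjusted p = 2.4e-04, and adjusted p = 0.465 with an estimated correlation. The sulfotransferase SOT17 (AT1G18590) fell from 214 ± 16.9 to 59.4 ± 3.5 CPM. Heat shock genes fell: 2 of 11 tested members were higher and 7 lower (the same counts adjusted over the list alone), with a median of -1.32. The heat shock list had camera adjusted p = 0.0399, and adjusted p = 0.496 with an estimated correlation. HSP70 (AT3G12580) fell from 286 ± 43.2 to 13.1 ± 1.15 CPM, and the list's call ended with a replicate block (camera adjusted p = 0.0521). Starch and sugar genes rose: 9 of 18 tested members were higher and 4 lower (the same counts adjusted over the list alone), with a median of 0.56. Camera gave the starch and sugar list adjusted p = 0.0307, and adjusted p = 0.465 with an estimated correlation. PHS2 (AT3G46970) rose by 2.95 ± 0.09 and GBSS1 fell by 3.51 ± 0.12. In edgeR 10487 genes passed, 5292 higher and 5195 lower at 2 than at 10 mM. Between 0 and 2 mM 7782 passed in WT, 3723 higher and 4059 lower at 0 mM. Of the anthocyanin genes, 20 of 25 tested members were higher and 2 lower (the same counts adjusted over the list alone), with a median of 2.55. The anthocyanin list had camera adjusted p = 3.2e-11, and adjusted p = 0.149 with an estimated correlation. Of the autophagy genes, 0 of 21 tested members were higher and 15 lower (the same counts adjusted over the list alone), with a median of -0.49. Camera gave the autophagy list adjusted p = 2.7e-04, and adjusted p = 0.228 with an estimated correlation.

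In era1 the response was likewise read from 0 against 10 mM. LHY rose there too, from 432 to 723 CPM, so the limit on time of day holds here as well. The nitrate transporter NRT2.5 (AT1G12940) had no counts at 10 mM and 20.5 ± 3.5 CPM at 0 mM, at least 118-fold higher. The cytosolic glutamine synthetase GLN1;4 (AT5G16570) rose from 4.03 ± 1.44 to 85.2 ± 13.8 CPM (4.40 ± 0.19, FDR = 1.8e-15), GSR 1 from 14.9 ± 1.89 to 118 ± 13.9 and the urea transporter DUR3 (AT5G45380) from 7.72 ± 0.787 to 57.2 ± 7.03. CLC-A fell from 143 ± 5.91 to 12.5 ± 3.20 CPM (-3.52 ± 0.11, FDR = 6.8e-18). The nitrogen-response repressors LBD39 (AT4G37540) and LBD38 (AT3G49940) fell from 31.8 ± 3.66 to 0.442 ± 0.253 and from 27.4 ± 7.2 to 1.95 ± 0.849 CPM, and BT2 was lower by a ratio of 155 (27.4 to 6167) (log2 fold change -6.77, and -8.51 without the era1 library 2 at 0 mM). The anthocyanin regulator MYB90 (AT1G66390) rose from 0.706 ± 0.533 to 123 ± 11.0 CPM (7.41 ± 0.22, FDR = 3.2e-18, and 8.07 without the era1 library 2 at 10 mM) and the plastid glucose 6-phosphate transporter GPT2 (AT1G61800) from 3.49 ± 0.275 to 204 ± 69.3. The galactolipid synthase MGDC (AT2G11810) rose from 0.468 ± 0.214 to 26.5 ± 3.76 CPM, the nitrilase NIT4 (AT5G22300) from 7.98 ± 0.578 to 162 ± 40.8 and the light stress protein ELIP1 (AT3G22840) from 24.1 ± 3.02 to 290.1 ± 48.8. Iron superoxide dismutase FSD1 (AT4G25100) fell from 121 ± 24.0 to 1.94 ± 2.78 CPM (log2 fold change -5.93, and -8.41 without the era1 library 2 at 0 mM). The edgeR test passed 10197 genes, 5054 higher and 5143 lower, with 1433 higher and 1438 lower by at least 2-fold.

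**Figure D5:**
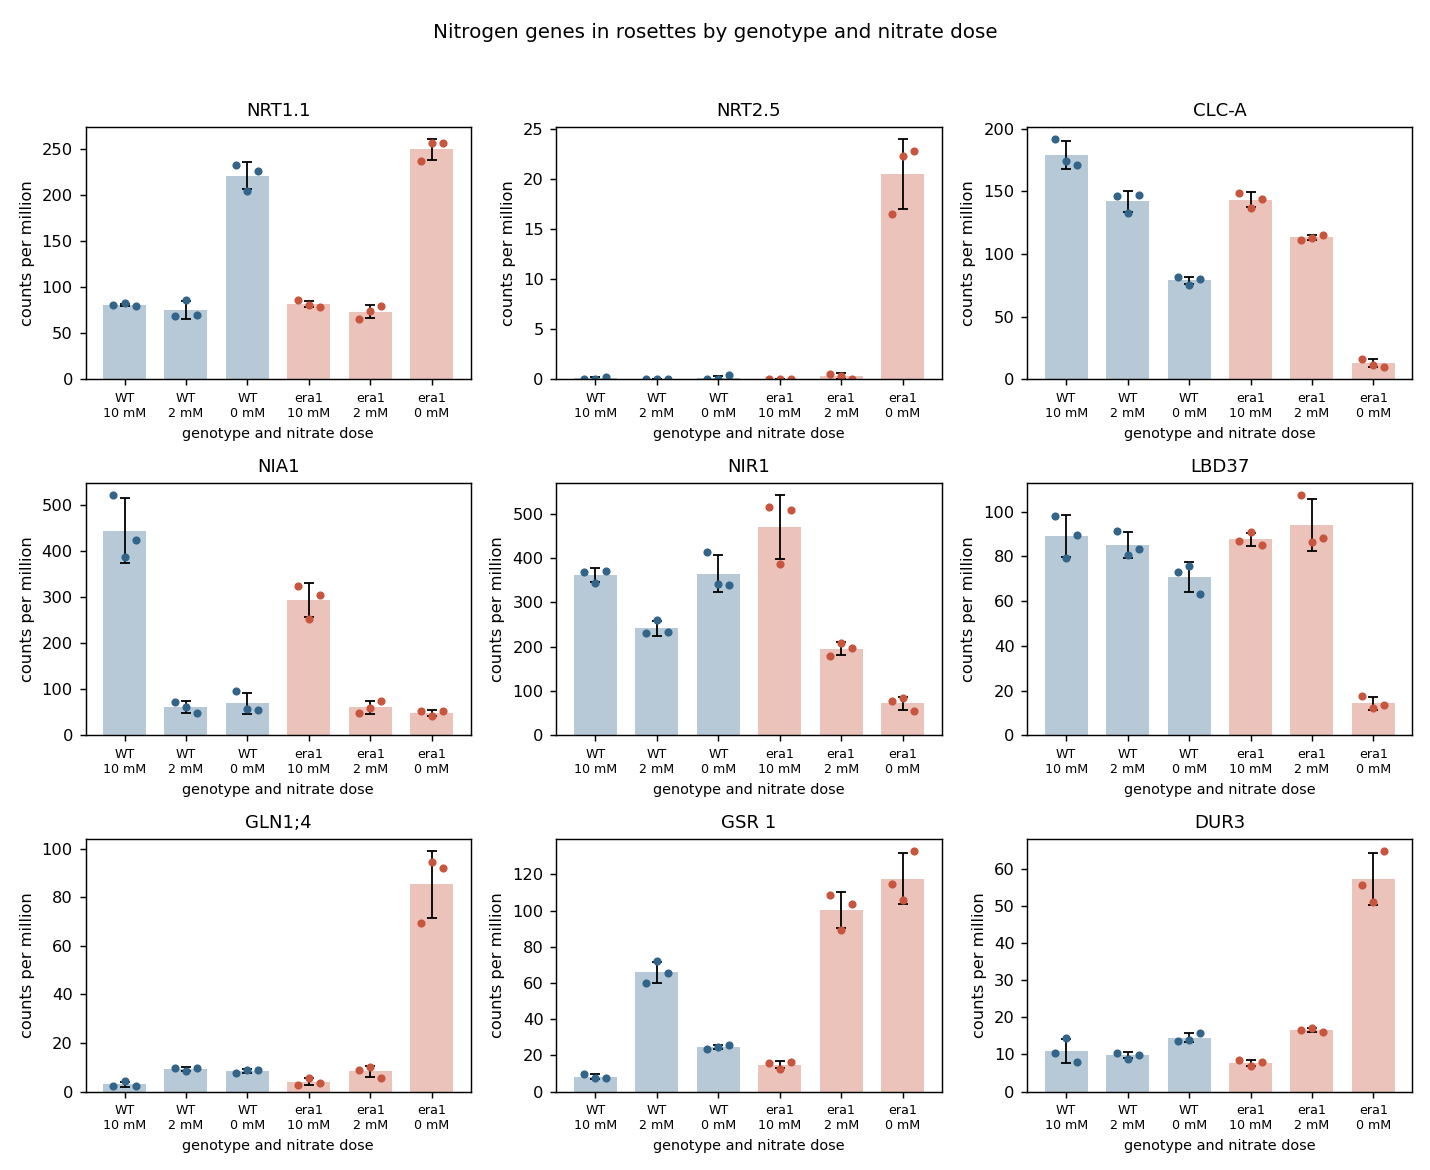
CPM (vertical axis) of 9 genes of nitrogen transport, assimilation and regulation by genotype and nitrate dose; points are single libraries, bars the mean of 3 and error bars the SD. NRT2.5 reached 20.5 CPM in era1 at 0 mM, and NIR1 stood at 72.2 CPM there against 365 CPM in WT.

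By lists, nitrate transport genes rose in era1 at 0 mM: 9 of 12 tested members were higher and 2 lower (the same counts adjusted over the list alone), with a median of 1.12. The nitrate transport list had camera adjusted p = 0.00619, and adjusted p = 0.0706 with an estimated correlation. Nitrate-induced genes fell: 3 of 23 tested members were higher and 19 lower (the same counts adjusted over the list alone), with a median of -1.74. Camera gave the nitrate-induced list adjusted p = 7.0e-08, and adjusted p = 0.0779 with an estimated correlation. Remobilisation and uptake genes rose: 11 of 14 tested members were higher and 2 lower (the same counts adjusted over the list alone), with a median of 0.63. The remobilisation and uptake list had camera adjusted p = 8.5e-05, and adjusted p = 0.0706 with an estimated correlation. ASN1 fell by 3.30 ± 0.38. Autophagy genes rose: 12 of 21 tested members were higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.26. Camera gave the autophagy list adjusted p = 0.0207, and adjusted p = 0.341 with an estimated correlation. ATG8G (AT3G60640) rose by 0.66 ± 0.13 and ATG8E fell by 0.77 ± 0.12. Leaf senescence genes rose: 10 of 17 tested members were higher and 3 lower (the same counts adjusted over the list alone), with a median of 0.68. The leaf senescence list had camera adjusted p = 0.0287, and adjusted p = 0.372 with an estimated correlation. That call ended without the era1 library 3 at 0 mM (camera adjusted p = 0.0618). SAG13 (AT2G29350) rose from 17.7 ± 3.92 to 93.5 ± 6.96 CPM. Anthocyanin and flavonoid genes rose: 23 of 25 tested members were higher and 1 lower (23 and 2 adjusted over the list alone), with a median of 1.61. Camera gave the anthocyanin list adjusted p = 2.0e-09, and adjusted p = 0.0779 with an estimated correlation. TT7 (AT5G07990) rose from 6.32 ± 1.1 to 60.3 ± 7.77 CPM and UF3GT from 10.8 ± 1.88 to 90.6 ± 1.07. Photosynthesis genes fell: 1 of 32 tested members were higher and 29 lower (the same counts adjusted over the list alone), with a median of -0.77. The photosynthesis list had camera adjusted p = 1.1e-12, and adjusted p = 0.228 with an estimated correlation. LHCB6 (AT1G15820) fell from 1655 ± 34.6 to 662 ± 81.4 CPM while RCA rose by 0.37 ± 0.07. Reads shared by near-identical copies of the RBCS and LHCB genes were set aside before counting, so single copies are uncertain. The organelle share in era1 at 0 mM was 3.25 ± 0.326% against 2.17 ± 0.349% of gene counts (exact permutation p = 0.1).

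Hormone and stress lists also moved in era1. Abscisic acid genes fell: 8 of 27 tested members were higher and 16 lower (the same counts adjusted over the list alone), with a median of -0.52. Camera gave the abscisic acid list adjusted p = 0.0307, and adjusted p = 0.507 with an estimated correlation. Without the era1 library 2 at 10 mM that camera adjusted p was 0.0563. The proline synthesis gene P5CS1 (AT2G39800) fell from 569.8 ± 88.4 to 105 ± 26.8 CPM and HB-12 (AT3G61890) rose by 0.91 ± 0.11. Jasmonic acid genes fell: 2 of 22 tested members were higher and 12 lower (the same counts adjusted over the list alone), with a median of -0.52. The jasmonic acid list had camera adjusted p = 0.0154, and adjusted p = 0.421 with an estimated correlation. VSP1 (AT5G24780) fell by 2.55 ± 0.31. The higher members moved further. PDF1.2 had a log2 fold change of 5.27, and of 4.51 without the era1 library 3 at 0 mM. PDF1.2b had a ratio of 26.8 (7.09 to 227) and a log2 fold change of 4.49. For PDF1.2b that value was 3.68 and no longer passed without the era1 library 3 at 0 mM, and was 7.08 without library 3 at 10 mM. Ribosome genes fell: 0 of 19 tested members were higher and 14 lower (the same counts adjusted over the list alone), with a median of -0.31. Camera gave the ribosome list adjusted p = 5.5e-04, and adjusted p = 0.321 with an estimated correlation. RPS6 (AT4G31700) fell from 322 ± 9.23 to 169 ± 10.4 CPM. Glucosinolate genes fell: 2 of 23 tested members were higher and 13 lower (2 and 14 adjusted over the list alone), with a median of -0.45. The glucosinolate list had camera adjusted p = 0.00799, and adjusted p = 0.372 with an estimated correlation. CYP79B3 (AT2G22330) fell from 56.1 ± 6.92 to 19.7 ± 3.65 CPM and IMS2 (AT5G23020) rose by 0.96 ± 0.13. Heat shock genes rose: 7 of 11 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.72. Camera gave the heat shock list adjusted p = 0.0204, and adjusted p = 0.372 with an estimated correlation. HSFA2 (AT2G26150) rose from 126 ± 8.31 to 326 ± 92.4 CPM. Starch and sugar genes rose: 11 of 18 tested members were higher and 2 lower (the same counts adjusted over the list alone), with a median of 0.68. The starch and sugar list had camera adjusted p = 1.8e-04, and adjusted p = 0.0779 with an estimated correlation. The amylase CT-BMY (AT4G17090) rose from 185 ± 10.9 to 609 ± 34.2 CPM.

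At 2 against 10 mM in era1 the clock genes CCA1 and LHY fell, by 2.79 ± 0.10 and 3.59 ± 0.09. Salicylic acid genes rose together with that difference: 14 of 18 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.95. Camera gave the salicylic acid list adjusted p = 5.8e-04, and adjusted p = 0.308 with an estimated correlation. CBP60G (AT5G26920), a regulator of salicylic acid synthesis, rose from 17.8 ± 3.37 to 111 ± 13.0 CPM. Jasmonic acid genes rose: 15 of 22 tested members were higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.61. The jasmonic acid list had camera adjusted p = 5.8e-04, and adjusted p = 0.308 with an estimated correlation. In this contrast camera called 11 of 19 lists, 7 higher and 4 lower at 2 mM, and the other called lists are not detailed here. WRKY53 rose from 6.45 ± 0.460 to 87.3 ± 25.9 CPM, GSR 1 rose from 14.9 ± 1.89 to 100.4 ± 10.1 and NIA1 fell by 2.27 ± 0.18. In edgeR 9540 genes passed, 4678 higher and 4862 lower at 2 than at 10 mM, and between 0 and 2 mM 9126 passed, 4347 higher and 4779 lower at 0 mM.

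The responses of both genotypes to 0 mM were compared across genes. Across 18358 genes the log2 fold changes of WT and era1 had a Pearson r of 0.487 and a Spearman rho of 0.482, and 77.2% of the genes called in WT had the same sign in era1. Genes are not independent replicates, and these comparisons share no libraries. 2699 genes were called higher in both (1361 would be shared by independent lists), 2756 lower in both (1372) and 926 in opposite directions (2734). The difference itself was tested as an interaction, in which positive values mean a higher change from 10 to 0 mM in era1. 6405 genes passed in edgeR, 2863 positive and 3542 negative, 935 and 1327 of them by at least 2-fold.

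Nitrite reductase NIR1 (AT2G15620) was at 362 ± 15.1 and 365 ± 41.4 CPM in WT at 10 and 0 mM, and at 470.4 ± 72.9 and 72.2 ± 15.1 CPM in era1 (interaction -2.72 ± 0.17, FDR = 2.0e-11). For NIA1 the interaction was 0.08 and did not pass (FDR = 0.828). LBD37 (AT5G67420) was at 89.0 and 70.7 CPM in WT and at 87.6 and 14.4 in era1 (-2.28 ± 0.17). Across the nitrate-induced genes, 3 of 23 tested members were positive and 13 negative (3 and 15 adjusted over the list alone), with a median of -0.80. Camera gave the nitrate-induced list adjusted p = 4.0e-05, and adjusted p = 0.247 with an estimated correlation. CLC-A (-2.34 ± 0.15) and SLAH3 (-1.32 ± 0.23) had negative and DUR3 (2.47 ± 0.23), GSR 1 (1.39 ± 0.21) and GLN1;4 (2.89 ± 0.42) positive interactions. Of the remobilisation and uptake genes, 6 of 14 tested members were positive and 1 negative (the same counts adjusted over the list alone), with a median of 0.19. The remobilisation and uptake list had camera adjusted p = 0.0224, and adjusted p = 0.292 with an estimated correlation. That call ended without the era1 library 2 at 10 mM (camera adjusted p = 0.0542). NIT4 was at 7.99 and 16.9 CPM in WT and at 7.98 and 162 in era1 (3.27 ± 0.34, FDR = 9.3e-08). MGDC (5.52 ± 0.70), the branched-chain aminotransferase BCAT-2 (AT1G10070) (3.84 ± 0.46), SUFE2 (AT1G67810) (3.45 ± 0.35) and proline dehydrogenase ERD5 (AT3G30775) (2.78 ± 0.38) had positive interactions. FSD1 (-7.32 ± 1.26, -9.80 without the era1 library 2 at 0 mM and -7.98 without the WT library 1 at 10 mM), LBD39 (-5.06 ± 0.37), the sulfur-deficiency genes LSU1 (AT3G49580) (-4.80 ± 0.55) and ATSDI1 (AT5G48850) (-3.35 ± 0.43), and nicotianamine synthase NAS1 (AT5G04950) (-3.60 ± 0.23) had negative ones.

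Several lists differed between genotypes in the response to 0 mM. Of the autophagy genes, 13 of 21 tested members were positive and 0 negative (the same counts adjusted over the list alone), with a median of 0.45. Camera gave the autophagy list adjusted p = 4.0e-05, and adjusted p = 0.163 with an estimated correlation. ATG8B (AT4G04620) was at 37.4 and 20.4 CPM in WT and at 37.8 and 45.0 in era1. Of the photosynthesis genes, 0 of 32 tested members were positive and 32 negative (the same counts adjusted over the list alone), with a median of -0.83. The photosynthesis list had camera adjusted p = 7.0e-21, and adjusted p = 0.163 with an estimated correlation. RBCS2B (AT5G38420), subject to the limit on copies, was at 1481 and 2119.7 CPM in WT and at 1241 and 635 in era1. Of the abscisic acid genes, 0 of 27 tested members were positive and 15 negative (the same counts adjusted over the list alone), with a median of -0.72. Camera gave the abscisic acid list adjusted p = 3.5e-04, and adjusted p = 0.348 with an estimated correlation. The transcription factor RD26 (AT4G27410) had -2.26 ± 0.17. Of the jasmonic acid genes, 0 of 22 tested members were positive and 9 negative (0 and 10 adjusted over the list alone), with a median of -0.81. The jasmonic acid list had camera adjusted p = 2.7e-04, and adjusted p = 0.348 with an estimated correlation. Lipoxygenase LOX2 (AT3G45140) had -2.58 ± 0.14. Of the salicylic acid genes, 9 of 18 tested members were positive and 1 negative (10 and 1 adjusted over the list alone), with a median of 0.84. Camera gave the salicylic acid list adjusted p = 6.6e-04, and adjusted p = 0.348 with an estimated correlation. WRKY54 (AT2G40750) was at 51.4 and 12.7 CPM in WT and 7.92 and 12.6 in era1. For phosphate starvation genes, 8 of 14 tested members were positive and 1 negative (9 and 1 adjusted over the list alone), with a median of 0.76. The phosphate starvation list had camera adjusted p = 4.2e-04, and adjusted p = 0.163 with an estimated correlation. For glucosinolate genes, 3 of 23 tested members were positive and 13 negative (3 and 15 adjusted over the list alone), with a median of -0.38. Camera gave the glucosinolate list adjusted p = 0.0106, and adjusted p = 0.510 with an estimated correlation. At 2 against 10 mM the interaction passed 2898 genes, 1413 positive and 1485 negative. For salicylic acid genes there, 14 of 18 tested members were positive and 0 negative (15 and 0 adjusted over the list alone), with a median of 1.73. The salicylic acid list had camera adjusted p = 1.6e-12, and adjusted p = 0.129 with an estimated correlation.

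At 10 mM nitrate, FSD1 was at 121 ± 24.0 against 0.345 ± 0.232 CPM in WT (log2 fold change 8.35 ± 0.41, FDR = 1.6e-13, and 9.01 without the WT library 1). The iron-deficiency regulators bHLH38 (AT3G56970), bHLH39 and BHLH100 (AT2G41240) were lower in era1, at 2.90 ± 0.894 against 85.2 ± 4.29, 3.42 ± 0.840 against 83.0 ± 4.0 and 6.53 ± 2.39 against 69.6 ± 2.71 CPM in WT. HSFA2 was at 126 ± 8.31 against 6.15 ± 1.82 CPM (4.36 ± 0.23, FDR = 5.5e-13) and the chaperone Hsp70-2 (AT5G02490) at 297 ± 8.46 against 23 ± 4.78. The lipid transfer protein LTP3 (AT5G59320) was at 355 ± 89.4 against 13.5 ± 5.26 CPM and LSU1 was higher by 3.63 ± 0.36. NUDT24 was at least 59.9-fold higher, and the senescence protease SAG12 (AT5G45890) higher by a ratio of 127 (43.3 to 619) (log2 fold change 6.84, and 7.71 without the WT library 2). ACD6 (AT4G14400) was at 164 ± 18.1 against 694 ± 19.7 CPM, the salicylic acid hydroxylase DMR6 (AT5G24530) at 38.4 ± 1.06 against 195 ± 22.0 CPM, and LURP1 (AT2G14560) (-2.34 ± 0.18) and WRKY54 (-2.69 ± 0.22) were lower. Clock genes lay apart between the genotypes as well. RVE1 (AT5G17300) was at 28.4 ± 2.98 CPM in era1 and 89.4 ± 1.28 in WT. GI (AT1G22770) ran from 22.5 to 27.2 CPM over the era1 libraries and from 11.4 to 12.8 over those of WT. LHY lay closer, at 432 CPM in era1 and 477 in WT. 5458 genes passed in edgeR, 2831 higher and 2627 lower in era1, with 515 higher and 439 lower by at least 2-fold.

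Among the lists at 10 mM, salicylic acid genes were lower in era1: 0 of 18 tested members were higher and 13 lower (0 and 14 adjusted over the list alone), with a median of -1.14. Camera gave the salicylic acid list adjusted p = 5.5e-06, and adjusted p = 0.314 with an estimated correlation. Phosphate starvation genes were lower: 0 of 14 tested members were higher and 9 lower (1 and 9 adjusted over the list alone), with a median of -0.51. The phosphate starvation list had camera adjusted p = 7.4e-05, and adjusted p = 0.202 with an estimated correlation. AT5G03545 was at 30.2 ± 8.42 against 386 ± 43.3 CPM. Heat shock genes were higher: 6 of 11 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.74. Camera gave the heat shock list adjusted p = 5.8e-05, and adjusted p = 0.314 with an estimated correlation. HSP90.1 (AT5G52640) was at 238 ± 25.3 against 48.0 ± 10.2 CPM. Anthocyanin genes were higher: 14 of 25 tested members were higher and 5 lower (15 and 5 adjusted over the list alone), with a median of 0.78. The anthocyanin list had camera adjusted p = 2.8e-04, and adjusted p = 0.314 with an estimated correlation. The regulator PAP1 (AT1G56650), or MYB75, was at 82.6 ± 11.2 against 9.12 ± 0.470 CPM, while PAL2 (AT3G53260) was lower (-0.47 ± 0.09). Abscisic acid genes were higher: 17 of 27 tested members were higher and 1 lower (17 and 4 adjusted over the list alone), with a median of 0.57. Camera gave the abscisic acid list adjusted p = 2.3e-04, and adjusted p = 0.407 with an estimated correlation. LTI65 (AT5G52300) was higher by 3.31 ± 0.49, and COR15A had the opposite direction (-1.29 ± 0.10). Jasmonic acid genes were higher: 10 of 22 tested members were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.46. The jasmonic acid list had camera adjusted p = 6.5e-04, and adjusted p = 0.410 with an estimated correlation. LOX2 was at 479 ± 5.77 against 155 ± 15.8 CPM. Photosynthesis genes were lower: 0 of 32 tested members were higher and 15 lower (the same counts adjusted over the list alone), with a median of -0.16. Camera gave the photosynthesis list adjusted p = 5.4e-04, and adjusted p = 0.593 with an estimated correlation. LHCA1 was at 2039 ± 76.8 against 2863 ± 53.2 CPM. The nitrate-responsive BT1 (AT5G63160) was at 57.1 ± 2.84 against 184 ± 33.5 CPM. Of the known farnesylated proteins, 3 of 7 tested members were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0595). The co-chaperones J3 (AT3G44110) (507 ± 23 against 310.1 ± 14.2 CPM) and J2 (0.64 ± 0.11) were higher. Beside these lists, the share of reads without a unique alignment was 2.52 ± 0.261% in era1 and 2.15 ± 0.222% in WT at 10 mM (exact permutation p = 0.1, the smallest possible).

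At 0 mM SAG12 was at 99.9 ± 32.0 against 1.05 ± 1.65 CPM in WT (6.51 ± 0.67, FDR = 1.6e-08, 9.70 without the WT library 3 and 5.92 without the WT library 1), GPT2 at 204 ± 69.3 against 2.41 ± 1.28, MYB90 at 123 ± 11.0 against 1.72 ± 0.431 and the nitrilase NIT2 (AT3G44300) at 83.8 ± 4.1 against 7.03 ± 1.19. Hsp70-2 was at 507 ± 154 against 32.0 ± 3.47 CPM and HSFA2 at 326 ± 92.4 against 26.2 ± 6.26. NRT2.5 was higher in era1 by a ratio of 163 (44.8 to 1352) (log2 fold change 7.10, and 9.79 without the WT library 3), GLN1;4 was at 85.2 ± 13.8 against 8.42 ± 0.764 CPM and LHT1 was higher by 1.87 ± 0.16. Lower in era1 were LBD39 (0.442 ± 0.253 against 13.8 ± 3.19 CPM), CLC-A (-2.66 ± 0.12), LEA3 (AT1G02820) (17.5 ± 3.08 against 204 ± 21.4 CPM), the growth regulator HBI1 (AT2G18300) (6.94 ± 0.549 against 69.2 ± 5.23 CPM), bHLH38 (-4.60 ± 0.56) and BHLH100 (-5.19 ± 0.59, and -6.08 without the era1 library 2). Among clock genes, RVE1 was at 44.3 ± 1.43 CPM in era1 and 96.4 ± 6.44 in WT. GI ran from 60.7 to 67.9 CPM over the era1 libraries and from 28.3 to 30.6 over those of WT. LHY lay closer, at 723 CPM in era1 and 740.0 in WT. 9014 genes passed in edgeR, 4491 higher and 4523 lower in era1, and 1069 were higher and 1349 lower by at least 2-fold.

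The photosynthesis list was lower in era1 at 0 mM: 0 of 32 tested members were higher and 32 lower (the same counts adjusted over the list alone), with a median of -1.0. The photosynthesis list had camera adjusted p = 2.1e-23, and adjusted p = 0.177 with an estimated correlation. RBCS2B was at 635 ± 98.9 against 2119.7 ± 216 CPM and LHCB6 at 662 ± 81.4 against 1684 ± 61.0. Autophagy genes were higher: 16 of 21 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.50. Camera gave the autophagy list adjusted p = 7.7e-06, and adjusted p = 0.177 with an estimated correlation. ATG8G was at 40.6 ± 3.00 against 16.9 ± 5.19 CPM and APG8A (AT4G21980) was higher by 0.91 ± 0.09. Nitrate-induced genes were lower: 2 of 23 tested members were higher and 15 lower (the same counts adjusted over the list alone), with a median of -0.91. The nitrate-induced list had camera adjusted p = 7.7e-06, and adjusted p = 0.177 with an estimated correlation. Remobilisation and uptake genes were higher: 8 of 14 tested members were higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.38. Camera gave the remobilisation and uptake list adjusted p = 0.00884, and adjusted p = 0.177 with an estimated correlation. Leaf senescence genes were higher: 9 of 17 tested members were higher and 3 lower (the same counts adjusted over the list alone), with a median of 0.68. The leaf senescence list had camera adjusted p = 0.00884, and adjusted p = 0.287 with an estimated correlation. SAG13 was higher (2.69 ± 0.17) and SEN1 lower (-2.31 ± 0.63). Heat shock genes were higher: 10 of 11 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 1.81. Camera gave the heat shock list adjusted p = 7.7e-06, and adjusted p = 0.177 with an estimated correlation. HSP90.1 was at 393 ± 117 against 68.5 ± 10.2 CPM. Anthocyanin genes were higher: 17 of 25 tested members were higher and 5 lower (18 and 6 adjusted over the list alone), with a median of 0.71. The anthocyanin list had camera adjusted p = 3.2e-05, and adjusted p = 0.214 with an estimated correlation. Starch and sugar genes were higher: 10 of 18 tested members were higher and 3 lower (the same counts adjusted over the list alone), with a median of 0.34. Camera gave the starch and sugar list adjusted p = 0.0208, and adjusted p = 0.287 with an estimated correlation. Glucosinolate genes were lower: 3 of 23 tested members were higher and 13 lower (3 and 14 adjusted over the list alone), with a median of -0.42. The glucosinolate list had camera adjusted p = 0.00784, and adjusted p = 0.381 with an estimated correlation. CYP79B3 was at 19.7 ± 3.65 against 71.2 ± 2.32 CPM, while IMS2 was higher (1.23 ± 0.13).

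The prenylation list itself was not called at 0 mM: 3 of 14 tested members were higher and 5 lower (the same counts adjusted over the list alone, camera adjusted p = 0.608). Its lower members include ERA1, the mutated gene, so these values are in part set by the genotype. Farnesyl diphosphate synthase FPS1 (AT5G47770) was at 63.9 ± 2.64 against 106 ± 1.86 CPM and RGTB1 (AT5G12210), a Rab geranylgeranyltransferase subunit, was higher by 0.68 ± 0.09. Of the farnesylated proteins, 4 of 7 tested members were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.221). J3 was higher by 0.51 ± 0.07 and BR6OX2 (AT3G30180), a brassinosteroid oxidase, lower (-0.63 ± 0.12). The root marker PYK10 was at 10.4 ± 3.63 against 24.7 ± 6.0 CPM (-1.26 ± 0.30, FDR = 0.00124). Organelle genes took 3.25 ± 0.326% of gene counts in era1 and 4.13 ± 0.184% in WT (exact permutation p = 0.1, the smallest possible).

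At 2 mM the clock gene LHY was at 35.9 CPM in era1 and 29.4 in WT, against 432 to 740.0 in the groups at the other doses. The genotypes also differed in clock genes at 2 mM, as RVE1 and GI did at 10 and 0 mM. LHY was higher in era1 (0.29 ± 0.10, FDR = 0.0446). ELF4 (AT2G40080) (-1.21 ± 0.23, FDR = 3.4e-04), PRR5 (-0.83 ± 0.23, FDR = 0.0094), FKF1 (-0.77 ± 0.23, FDR = 0.019) and RVE1 (AT5G17300) (-0.70 ± 0.20, FDR = 0.0145) were lower. The values below stand beside that clock difference. HSFA2 was at 51.2 ± 1.55 against 1.12 ± 0.639 CPM in WT (5.47 ± 0.34, FDR = 3.1e-11) and HSP70 at 122 ± 6.53 against 13.1 ± 1.15. Heat shock genes were higher: 8 of 11 tested members were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 1.99. Camera gave the heat shock list adjusted p = 1.2e-11, and adjusted p = 0.106 with an estimated correlation. Jasmonic acid genes were higher: 14 of 22 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.77. The jasmonic acid list had camera adjusted p = 2.9e-08, and adjusted p = 0.186 with an estimated correlation. JAZ5 (AT1G17380) was at 36.0 ± 11.5 against 7.84 ± 1.83 CPM and LOX3 (AT1G17420) at 58.8 ± 18.5 against 12.8 ± 1.59. Salicylic acid genes were higher: 9 of 18 tested members were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.55. Camera gave the salicylic acid list adjusted p = 1.0e-04, and adjusted p = 0.242 with an estimated correlation. GRX480 (AT1G28480) was at 16.6 ± 1.29 against 1.42 ± 0.278 CPM. Leaf senescence genes were higher: 13 of 17 tested members were higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.61. The leaf senescence list had camera adjusted p = 2.0e-06, and adjusted p = 0.155 with an estimated correlation. WRKY53 was at 87.3 ± 25.9 against 23 ± 3.68 CPM and SEN1 was lower (-0.96 ± 0.17). Photosynthesis genes were lower: 0 of 32 tested members were higher and 27 lower (0 and 29 adjusted over the list alone), with a median of -0.37. Camera gave the photosynthesis list adjusted p = 1.3e-14, and adjusted p = 0.211 with an estimated correlation. PSAF (AT1G31330) was at 2465 ± 86.4 against 3366 ± 16.6 CPM. J2 was at 115 ± 0.885 against 49.2 ± 3.71 CPM and J3 at 362 ± 18.9 against 191 ± 8.32. Organelle genes took 3.44 ± 0.152% of gene counts in era1 and 3.95 ± 0.130% in WT (exact permutation p = 0.1). 4040 genes passed in edgeR, 2006 higher and 2034 lower in era1.

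Averaged over doses, HSFA2 (4.49 ± 0.14, FDR = 6.8e-18), Hsp70-2 (3.82 ± 0.12), PPI2 (AT3G15340) (4.35 ± 0.22), UF3GT (3.15 ± 0.23, and 4.50 without the WT library 3 at 2 mM), DFR (AT5G42800) (2.75 ± 0.13) and GSTF12 (AT5G17220) (2.79 ± 0.13) were higher in era1. The flowering repressor MAF5 (AT5G65080) was lower in era1, at 6.80, 6.88 and 10.9 CPM at 10, 2 and 0 mM against 28.6, 43.3 and 26.0 in WT (-1.99 ± 0.10, FDR = 3.7e-14). CLC-A was lower (-1.1 ± 0.06) and the nitrate transporter NRT1.5 (AT1G32450) higher (1.1 ± 0.10). J2 (0.80 ± 0.06) and J3 (0.71 ± 0.04) were higher and FPS1 lower (-0.50 ± 0.04). Photosynthesis genes were lower: 0 of 32 tested members were higher and 32 lower (the same counts adjusted over the list alone), with a median of -0.52. The photosynthesis list had camera adjusted p = 2.2e-20, and adjusted p = 0.165 with an estimated correlation. Heat shock genes were higher: 11 of 11 tested members were higher and 0 lower (the same counts adjusted over the list alone), with a median of 1.65. Camera gave the heat shock list adjusted p = 1.3e-08, and adjusted p = 0.165 with an estimated correlation. 8645 genes passed in edgeR, 4365 higher and 4280 lower, and 8128 passed without the 2 mM libraries, an alternative chosen after the clock genes were seen. Between 10 and 0 mM the genotype differences had a Pearson r of 0.332 and a Spearman rho of 0.223 across genes.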

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

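Of the tests in this part, the scaling test of the interaction and the bootstrap interval of its clock test were chosen only after the result was seen.

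The change from 10 to 0 mM nitrate differed between era1 and WT in 6405 genes in edgeR's interaction test, and the change from 10 to 2 mM in 2898. Of 100 splits of the libraries by genotype within each dose, 1, the real split, called as many genes at 0 mM, and the highest of the others called 3975. At 2 mM 1 of 100 was as large, and the highest other split called 336. The other splits mix the genotypes within groups, so any genotype difference widens their spread. They therefore cannot tell a chance interaction from a genotype difference that is alike at all doses. For the genotype difference averaged over doses, 8645 genes were called and the highest other split called 3139. There 1 of 100 was as large, which argues against a chance split for that count. For the 9 contrasts of single groups the 10 splits of 6 libraries are too few for a share under 0.05. There the real split called 4040 to 10487 genes, 1 split of 10 was as large, and the highest other called 0, or 1 for WT at 0 against 2 mM.

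The interaction at 0 mM was weighed against technical explanations. A shift in scaling between libraries would add nearly the same log2 value to every gene. With any constant shift from -3 to 3 removed, at least 6395 genes still passed, against 6420 with no shift in the same computation. The median interaction was already -0.011 after TMM scaling, so little was left to remove and this outcome was near certain. The values show only that no constant shift left after TMM makes the calls. Shifts that vary between genes were not tested. A different time of day at harvest could move clock outputs apart between the genotypes. Their evening and morning medians differed by 0.34 in the interaction. That value lies under the bound of 0.5 set for excluding this explanation, yet its 95% bootstrap interval over genes ran from -1.02 to 0.89, so it decides nothing and the explanation stays open. A difference of genotype in the response to nitrate, the contrast that the design names, also stays open.

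Gene lists differed between genotypes by the same interaction test in camera, though 0 of these calls held in camera with an estimated correlation (3 and 2 lists had an unadjusted p under 0.05 at 0 and 2 mM, and fry called 12 and 6). At 0 mM the median interaction was -0.80 for nitrate-induced genes, 0.19 for remobilisation and uptake, 0.45 for autophagy, -0.83 for photosynthesis, -0.72 for abscisic acid, 0.84 for salicylic acid, -0.81 for jasmonic acid, 0.76 for phosphate starvation and -0.38 for glucosinolate genes. The remobilisation call ended without the era1 library 2 at 10 mM (camera adjusted p = 0.0542). At 2 mM it was 0.45 for leaf senescence, -0.20 for photosynthesis, 1.73 for salicylic acid, 0.54 for phosphate starvation, 0.25 for glucosinolate and 0.70 for heat shock genes. The photosynthesis call at 2 mM ended in fry (fry adjusted p = 0.0504).

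Single genes also differed between genotypes in the change from 10 to 0 mM, which need not mean a difference at 0 mM. Positive interactions were 5.52 for MGDC, 4.86 for GLYI4 (3.72 without the era1 library 3 at 0 mM), 4.22 for NAC004 and 3.84 for BCAT-2. Also positive were ELI3-2 (3.46), SUFE2 (3.45), NIT4 (3.27), GLN1;4 (2.89), RAP2.9 (2.78) and ERD5 (2.78). Negative ones were -7.32 for FSD1 and -5.63 for LTI65 (-9.80 and -7.99 without the era1 library 2 at 0 mM, which held most of their counts there, and -7.98 for FSD1 without the WT library 1 at 10 mM), -5.06 for LBD39, -4.80 for LSU1, -3.72 for GRP9 (-4.57 without the era1 library 1 at 0 mM), -3.60 for NAS1, -3.59 for LTP3, -3.50 for VSP1, -3.38 for NATA1 (-4.82 without the WT library 1 at 10 mM and -2.72 without the WT library 1 at 0 mM) and -3.35 for ATSDI1. Over its 3 libraries NIT4 had 2984 counts in era1 at 0 mM and 115 to 268 in the other groups at 10 and 0 mM, while LBD39 had 8 in era1 at 0 mM and 218 to 548. FSD1 differed mainly at 10 mM, with 2086 counts in era1 at 10 mM and 36 at 0 mM, against 5 and 15 in WT.

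Reads without a unique alignment, which no gene comparison uses, had a higher share than in the 10 mM controls of their genotype (2.15% in WT, 2.52% in era1). The share was 4.88% in WT at 2 mM, 4.97% in WT at 0 mM, 4.72% in era1 at 2 mM and 4.74% in era1 at 0 mM.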

How the results depend on the processing

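Of the tests in this part, leaving out the libraries grown at 2 mM was chosen only after the result was seen. Counts of genes past the threshold stayed within 1.5 times their value under every alternative run. Leaving out 1 library at a time gave 8867 to 9275 genes for WT at 0 against 10 mM, 9500 to 9828 at 2 against 10 and 6791 to 7421 at 0 against 2. In era1 the ranges were 9039 to 9600, 8403 to 9062 and 8181 to 8527. Between genotypes they were 4104 to 5404 at 10 mM, 2933 to 3763 at 2 mM, 7789 to 8623 at 0 mM and 8193 to 8683 averaged over doses, and for the interactions 5508 to 6671 at 0 mM and 2070 to 3197 at 2 mM. The DESeq2 test called 8598 genes for WT at 0 against 10 mM and 4271 between genotypes at 10 mM. Without the libraries grown at 2 mM the counts were 9629 for WT and 9886 for era1 at 0 against 10 mM, 5174 and 8710 between genotypes at 10 and 0 mM, 8128 averaged and 6194 for the interaction. ERA1 lay between -2.41 and -2.29 when averaged over doses with 1 library left out. With the estimated correlation, camera called 0 lists in each of the 12 contrasts (0 to 5 at an unadjusted p under 0.05), so 0 of the 104 calls made with the preset one held. fry called 18 for WT at 2 against 10 mM, 13 for WT and 14 for era1 at 0 against 2 mM, and 11, 14 and 16 between genotypes at 10, 2 and 0 mM. The camera runs differed only in the inter-gene correlation, so the 104 calls rest on the preset value of 0.01. The Pearson r between the responses of WT and era1 to 0 mM was 0.556 over genes with a mean of at least 5 CPM, against 0.487, and 0.454 to 0.510 with 1 library left out; the cause was not tested. CBP60G averaged over doses went from 0.38 to -0.015 without the libraries grown at 2 mM, an average over fewer doses. No other named value that was called in the main fit was reversed under the alternatives run. Named gene values called in the main fit counted as the same if they kept direction and call. Values not called there had to stay uncalled, but any whose sign changed also counted as the same. By that rule 955 of 960 were the same with DESeq2 size factors, 954 with upper-quartile factors and 899 of 958 in the DESeq2 test. The counts were 939 of 960 in limma-voom, 948 with no expression filter and 7373 of 7824 with 1 library left out. Lists held in 820 of 834 cases with 1 library left out. Without the era1 library 1 or 3 at 0 mM, or 1 or 3 at 2 mM, nitrate transport genes lost the call for era1 at 0 against 2 mM (camera adjusted p = 0.0660, 0.0608, 0.0611 and 0.0630), and without the WT library 2 at 10 mM or 3 at 2 mM salicylic acid genes lost theirs for WT at 2 against 10 mM (0.0951 and 0.0795). With the replicate number as a block the counts were 9800, 10424 and 7709 for WT, 10130, 9483 and 9050 for era1 (0 against 10, 2 against 10 and 0 against 2 mM), 5363, 3994, 8944 and 8578 between genotypes (10, 2 and 0 mM and averaged), and 6335 and 2800 for the interactions. The numbers share no more than a name in this pairing check, as 1 of 45 pairs of libraries with a common number had a correlation of deviations over 0.1 and 5 of 18 libraries correlated best with their own number. The block ended 3 of 104 list calls. At this depth, in simulated libraries 25.4% of 1.5-fold interactions were recovered, with 17822 of 18053 genes left unchanged. In the data 6405 of 18358 genes passed the interaction at 0 mM, which makes the FDR cut-off less strict. The simulated share therefore need not hold in the data, where small interactions can still go undetected.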

Other observations

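Of the tests in this part, that of depth for the 2 mM libraries and the bootstrap intervals were chosen only after the result was seen, the clock outputs were chosen after the values of the core clock genes, and the metal genes after the values of bHLH38, bHLH39, BHLH100 and FSD1.

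Levels of metal genes at the 3 doses are given as values only. In WT the iron-deficiency regulator bHLH38 was at 85.2 ± 4.29 CPM at 10 mM, 5.98 ± 1.79 at 2 mM and 17.8 ± 2.82 at 0 mM, and BHLH101 at 24.4 ± 1.88, 7.24 ± 1.85 and 9.64 ± 2.00 CPM (SD, n = 3). In era1 bHLH38 was at 2.90 ± 0.894, 11.4 ± 10.6 and 0.718 ± 0.214 CPM, and BHLH101 at 6.38 ± 1.21, 5.93 ± 1.85 and 1.54 ± 0.251. The ferric reductase FRO3 was at 59.7 ± 3.53 CPM at 10 mM and 21.3 ± 3.30 at 0 mM in WT, and at 35.2 ± 2.4 and 11.1 ± 1.17 CPM in era1. The ferritin FER1, which stores iron, was at 33.0 ± 3.55 CPM at 10 mM and 112 ± 16.1 at 0 mM in WT, and at 53.1 ± 8.04 and 136 ± 31.3 CPM in era1. FER3 was at 89.9 ± 5.26 CPM at 10 mM and 51.1 ± 8.25 at 0 mM in WT and at 53.4 ± 5.30 and 21.8 ± 3.01 in era1. At the same doses FER4 was at 21.6 ± 2.92 and 33.0 ± 3.64 CPM in WT and at 21.8 ± 1.9 and 25.8 ± 3.26 in era1, and the transporter OPT3 at 191 ± 19.8 and 189.8 ± 10.2 CPM in WT and at 182 ± 13.0 and 169.6 ± 19.9 in era1. FSD1 was at 121 ± 24.0 CPM in era1 at 10 mM, and its mean in the other groups was 0.345 to 1.94 CPM.

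At 10 mM bHLH38, bHLH39 and BHLH100 were lower and FSD1 higher in era1, and metal status was weighed as a hypothesis. Copper deficiency could raise FSD1 and lower the copper proteins CSD1, CSD2 and CCS, whose values were 0.19, -0.37 and -0.49 with a median of -0.37, between the bounds of -0.5 and -0.2 set for and against it. A lower iron-deficiency response had a median of -0.30 over the other markers, with BHLH101 (-1.93), FRO3 (-0.76) and PYE (-0.44) lower and NAS4 (-0.06), BTS (-0.16) and OPT3 (-0.07) not past the test, so it stays open. More stored iron had a median of 0.010 over ferritins that went both ways, FER1 at 0.69, FER3 at -0.75 and FER4 at 0.01, which decides nothing, a reading set after the value, under the bound of 0.2 against this explanation, was seen. Technical explanations were not tested beyond the alternative scalings, under which no named value called at 10 mM was reversed.

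The libraries grown at 2 mM stood apart from those at 0 and 10 mM in both genotypes. Depth is argued against, as 5 of the 6 libraries had totals inside the range of the other libraries of their genotype. A different time of day at harvest may account for the pattern: over clock outputs outside the core clock list, the evening median (4 genes) exceeded the morning median (9 genes) by 3.77 in WT (95% bootstrap interval 1.93 to 5.62) and by 3.19 in era1 (1.81 to 4.18). A difference was predicted before these outputs were measured, but after the core clock genes had been seen to move. Clock outputs move with the core clock whatever shifts it, so they add no independent evidence for the harvest time. The labels used here give no harvest time, and a response of the clock to 2 mM nitrate or plants grown apart from the others were not tested and stay open. For 0 against 10 mM the intervals of the same clock outputs reached past 0.5 on both sides of 0, so a different time of day stays open there too.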
